A study of Mus musculus with 11 samples.

How the data were processed

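Bulk RNA-seq of sorted ILC2s was analysed from 11 libraries, 3 of kidney, 4 of lung and 4 of small-intestine lamina propria, all from naive C57BL/6 mice per the labels. Per the labels' protocols, leukocytes were isolated by digestion and a percoll gradient, followed by erythrocyte lysis and enrichment with CD45 beads for kidney and by erythrocyte lysis for lung. Cells of kidney and lung were sorted as positive for CD45, CD127, CD25 and Sca-1 and negative for lineage markers, and those of small intestine with KLRG1 in place of Sca-1. The isolation thus goes with the organ, and the gate sets small intestine apart from kidney and lung. RNA was extracted from the sorted cells and made into cDNA libraries.

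The authors deposited raw counts per gene, 1 table for the whole series, and per the submitters' processing notes the tools were Trimmomatic 0.38, STAR 2.5.4b, R 4.03, DESeq and DESeq2 1.39 with genome build GRCm38. The roles of these tools, the counting program, its annotation and its use of strand are not given in the sources used here. The table held 19069 genes with at least 5 counts in all libraries together and no gene of the mitochondrial genome, so that mitochondrial content was not measured. Ensembl identifiers were matched to GENCODE M21 (GRCm38) for symbols and coordinates; 18903 matched and the other 166 were kept without a name. Reads of near-identical copies and of overlapping or antisense genes may have been split or dropped by the counting.

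The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, the filter filterByExpr on the groups and 1 design over all 11 libraries with a mean per organ. It tested 13291 genes, had 8 residual degrees of freedom and a common biological coefficient of variation of 0.202. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over all tested genes). Every adjusted p of a gene is from this test unless another is named. The standard error of a log2 fold change is its size divided by the square root of F. CPM values were computed from the deposited counts with library totals scaled by the TMM factors, and are given as mean ± SD over the libraries of an organ. Where the lower group had no count, a fold is a lower bound against a floor of 3 counts over the group's libraries; with 1 to 3 counts, the ratio is given with its exact 95% Poisson interval. Floors and intervals cover counting error only. The library totals of 8395744 to 14039194 put the level of 3 counts in 1 library at 0.214 to 0.357 CPM. Fold changes were not corrected for GC content; across genes their rank correlation with it was -0.152 for small intestine over lung, -0.234 for small intestine over kidney and -0.06 for lung over kidney.

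The design, the comparisons, the alternatives, 35 gene lists and the rule for naming genes were fixed before the data were examined. By that rule, the text takes its genes from the 10 with the largest fold change per direction and comparison (adjusted p under 0.05, at least 20 CPM in the higher group, no overlap between libraries, without unnamed gene models, immunoglobulin and T cell receptor segments and markers of other cells), from up to 2 called members per direction and comparison of each list, and from Ccr9, Itgb7, Itga4, Rarb, Rara, Il1rl1, Il17rb, Il18r1, Gata3, Rora, Areg, Il5, Il13, Nmur1, Arg1, Klrg1 and Ly6a, the last 2 only as a check of the sort, as for Il7r, Il2ra and Ptprc. A gene named for 1 comparison may also be given for another. Lists with at least 5 tested genes (30 lists, 90 pairs of list and comparison) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all pairs. Camera compares a list with the other genes. It called 38 pairs, against 5 with an estimated correlation, and fry, which asks only whether a list moves one way on balance, called 60.

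The labels do not say whether the libraries of an organ came from separate mice, so that p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 8.26). Whether the replicate numbers of the titles pair libraries across organs was checked from deviations from the group means: in small intestine and lung, same-numbered libraries correlated with r of 0.156 to 0.296 in all 4 pairs, and differently numbered ones with -0.357 to 0.247. Differently numbered libraries within replicates 1 and 2 or 3 and 4 correlated with 0.096 to 0.247, and the others with -0.357 to -0.085. The correlations thus also follow this division of the libraries, so that pairing cannot be told apart from it. The labels give no pairing. The main test used none, and the fit with the number as a block is given where it changes a call.

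The fits of edgeR, DESeq2 and limma-voom and the list test were tested on simulated counts with known changes. These were drawn from the means and library sizes of these data, each gene independently of the others. They therefore cannot judge the preset correlation of the list test. Only the results of edgeR are given here. The other steps were not tested in this way. edgeR recovered 25.4% of 67 genes changed 1.5-fold, 71.6% of 67 changed 2-fold and 87.9% of 66 changed 4-fold for small intestine against lung, 13.4%, 52.2% and 84.8% for small intestine against kidney and 22.4%, 67.2% and 92.4% for lung against kidney, with 8, 5 and 7 unchanged genes called. Most simulated changes of 1.5-fold were missed. Far fewer genes were changed in the simulations than were called in the data, which makes the adjusted threshold stricter. These shares may therefore not carry over to the data. Alternatives were size factors in the manner of DESeq2, no filter or a filter of 10 counts in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, fits of 2 organs alone, the replicate block, each library left out, a threshold of 0.01, a prior count of 0.5 and, chosen after seeing the data, subsets of replicates 1 and 2 or 3 and 4 and a term for them. The subsets kept all kidney libraries.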

Results

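RNA was sequenced from group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that make type 2 cytokines, sorted from the kidney (3 libraries), the lung (4 libraries) and the small-intestine lamina propria (4 libraries) of naive C57BL/6 mice. The stated purpose was to learn how the organ of origin shapes the transcriptome of these cells, and the title of the series ties the intestinal program to retinoic acid. The libraries held 8395744 to 14039194 counts over 19069 genes. Within an organ, the correlation of log2 CPM between libraries was 0.962 to 0.989, and between organs it was 0.859 to 0.928. The first component of the 500 most variable genes held 56.8% of their variance and the second 34.5%, and the libraries of each organ lay together.

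**Figure D1:**
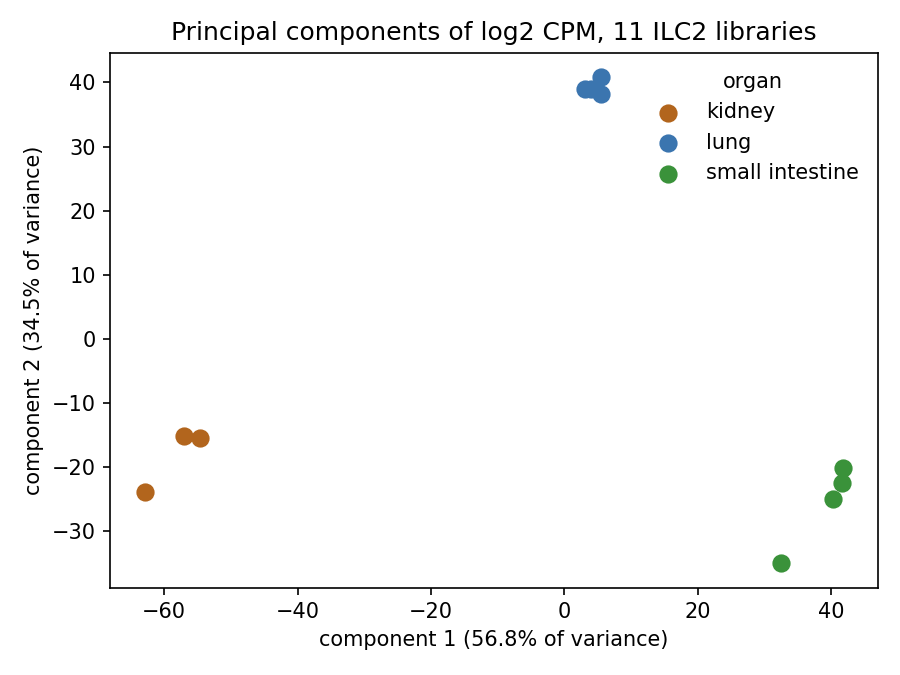
Each point is 1 library, placed by its first and second principal component of log2 CPM over the 500 most variable genes and coloured by organ. The libraries of each organ lie together and apart from those of the other organs, with kidney replicate 1 and small intestine replicate 1 at some distance from the rest of their groups.

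The genes behind the sort gates were measured as a check of the sort. Kidney and lung ILC2s were gated on Sca-1, encoded by Ly6a, and intestinal ILC2s on KLRG1. Klrg1 was at 1129 ± 73.8 CPM in small intestine, 730 ± 86.4 in lung and 381 ± 21.2 in kidney (SD). Ly6a was at 641 ± 77.2 CPM in small intestine, 746 ± 107 in lung and 1571 ± 158 in kidney. Transcripts of the gates shared by all organs were abundant everywhere. Il7r, which encodes CD127, was at 578 ± 75.8, 650 ± 35.4 and 628 ± 77.8 CPM in small intestine, lung and kidney. In the same order, Il2ra (CD25) was at 427 ± 22.9, 555 ± 94.7 and 460 ± 22.9 CPM and Ptprc (CD45) at 929 ± 159, 1160 ± 68.1 and 701 ± 43.2 CPM. Kidney and lung shared a gate, and small intestine had another, while the isolation steps differed between organs. An effect of the gate cannot be separated from the organ in the comparisons with small intestine. An effect of the isolation cannot be separated from it in any comparison that follows.

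Small-intestinal ILC2s differed from lung ILC2s in 4823 genes, with 2428 higher in small intestine and 2395 higher in lung. At least 2-fold changes were counted for 973 and 1043 of them. The genes with the largest changes included Atp8a2, a phospholipid flippase, at 418 ± 38.4 CPM in small intestine against 0.432 ± 0.296 in lung (967-fold). Tff2 and Gkn3 were also among them but lay mainly in small intestine replicate 1, at 191 and 214 CPM. In the other small intestine libraries they were at 2.08 to 32.7 and 1.31 to 11.4 CPM. Which cells these transcripts came from was not tested. Scin, an actin-severing protein, was at 91.4 ± 30.7 against 0.184 ± 0.205 CPM. Kmo is an enzyme of tryptophan breakdown. Kmo had 3 counts in all lung libraries together, which gave a ratio of 611 with a 95% counting interval of 171 to 2422. On the lung side was Sema4a, a semaphorin, at 1003 ± 95.7 against 19.1 ± 6.64 CPM. Ccr2, a chemokine receptor of circulating myeloid cells and activated lymphocytes, was at 1203 ± 211 against 36.4 ± 16.0 CPM. Ramp1, a subunit of the receptor for calcitonin gene-related peptide, was at 744 ± 143 against 25.4 ± 5.90 CPM. The log2 fold changes of small intestine over lung were -6.02 ± 0.35 for Mmp9, a gelatinase, and -6.72 ± 0.26 for Ache, which encodes acetylcholinesterase (SE).

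Genes known to be induced by retinoic acid were mostly higher in small intestine. Of the 7 tested genes of the retinoic acid response list, 6 were higher in small intestine than in lung and 1 was lower, and adjusted over the list alone the counts were also 6 and 1. The list passed the competitive test (camera adjusted p = 0.00116), with an adjusted p = 0.0681 with an estimated correlation. Hic1, a transcriptional repressor (ENSMUSG00000043099, chromosome 11, 75164565 to 75169519 of GRCm38, minus strand, protein-coding), was at 228 ± 27.2 CPM in small intestine and 1.45 ± 0.830 in lung, a log2 fold change of 7.30 ± 0.32 (edgeR adjusted p = 1.62e-09). Tgm2, a transglutaminase, was at 217 ± 47.1 against 2.16 ± 0.843 CPM. Ccr9, the receptor for the small-intestinal chemokine CCL25 (ENSMUSG00000029530, chromosome 9, 123678439 to 123784330, plus strand), was higher by a log2 fold change of 0.82 ± 0.15 (adjusted p = 0.000988). The member that was lower in small intestine was Rarg, a retinoic acid receptor, at 7.82 ± 0.469 against 124 ± 16.7 CPM. Rarb, another receptor and a known target, had too few counts to be tested. Of the 6 tested genes for synthesis and receptors of retinoic acid, 1 was higher and 2 were lower in small intestine, and the list did not pass the test (camera adjusted p = 0.931). Its higher member was Rxrg, at 264 ± 51.3 against 50.9 ± 9.59 CPM, and Rara was lower by a log2 fold change of -0.59 ± 0.16 (adjusted p = 0.0107). The call of Rara was lost within replicates 1 and 2 and within replicates 3 and 4 of the 2 organs (adjusted p = 0.0859 and 0.0864), with log2 fold changes of -0.58 and -0.59. Stromal markers moved with this comparison. The 14 genes of that list summed to 189 to 308 CPM in small intestine, 38.2 to 50.5 in lung and 83.2 to 354 in kidney. Most of the sum in small intestine came from Pdgfrb, at 83.7 to 127 CPM, and Pecam1, at 98.95 to 200.4 CPM. In lung, most of it came from Pecam1, at 36.8 to 48.7 CPM. The sums of these organs therefore say little about the other genes of the list.

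The receptors for the alarmins were divided between the organs. Il17rb, which encodes the receptor subunit for interleukin-25 (ENSMUSG00000015966, chromosome 14, 29996135 to 30008896, minus strand), was at 1398 ± 135 CPM in small intestine and 219 ± 23.1 in lung. This was a log2 fold change of 2.68 ± 0.13 (adjusted p = 2.67e-09). Il1rl1, which encodes the receptor for interleukin-33 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415, plus strand), was at 173 ± 32.1 against 1488 ± 292 CPM with a log2 fold change of -3.11 ± 0.17 (adjusted p = 1.02e-08). Il18r1, a subunit of the interleukin-18 receptor, was low in all 3 organs, at 3.88 ± 0.610 CPM in small intestine, 3.61 ± 0.788 in lung and 1.54 ± 1.19 in kidney. Of the 19 tested alarmin and cytokine receptors, 13 were lower in small intestine than in lung and 2 were higher, both over all genes and adjusted over the list alone. Camera gave an adjusted p of 0.000298, with an adjusted p = 0.038 with an estimated correlation. Il10ra was among the lower ones, at 41.3 ± 21 against 590 ± 58.3 CPM. Of 12 tested chemokine receptors, 6 were lower and 2 higher in small intestine (8 and 2 adjusted over the list alone). The camera adjusted p was 0.0293, with an adjusted p = 0.441 with an estimated correlation. Ccr2 was among the lower ones and Ccr4 was higher, at 278 ± 59.3 against 45.9 ± 5.27 CPM.

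Effector genes moved in both directions, with 6 of 17 tested higher in small intestine and 9 higher in lung. The counts were the same adjusted over the list alone, and the list did not pass the test (camera adjusted p = 0.428). Il4 was at 210 ± 72.9 CPM in small intestine and 11.5 ± 3.92 in lung, and Il6 at 39.7 ± 21.8 against 2.55 ± 1.24 CPM. Il5, the cytokine that recruits and sustains eosinophils, was at 83.4 ± 47.2 against 199 ± 33.8 CPM (log2 fold change -1.26 ± 0.31, adjusted p = 0.00607), with log2 fold changes of -1.98 within replicates 1 and 2 and -0.83 within replicates 3 and 4. Ccl1, which encodes a ligand of CCR8, was at 50.6 ± 30.7 against 545 ± 204 CPM. Il13 was at 16.0 ± 14.1 against 3.56 ± 2.31 CPM with overlap between the libraries. Its adjusted p of 0.0222 rose to 0.0578, 0.0616, 0.0684 and 0.0785 without lung replicate 1, lung replicate 2, small intestine replicate 3 and small intestine replicate 4, to 0.0667 with limma-voom and to 0.149 within replicates 1 and 2, where the log2 fold change was 1.15 in place of 2.21. Areg, which encodes the repair factor amphiregulin, was at 214 ± 181 against 259 ± 70.0 CPM, and the difference was smaller than the spread between libraries (adjusted p = 0.723). The log2 fold change of Areg was -1.85 within replicates 1 and 2 (adjusted p = 0.00163) and 0.31 within replicates 3 and 4 (adjusted p = 0.395). Among the receptors for neuropeptides and lipid mediators, 8 of 18 tested were higher in small intestine and 7 lower (8 and 8 adjusted over the list alone; camera adjusted p = 0.547). Nmur1, the receptor for neuromedin U, was at 1368 ± 139 against 484 ± 15.7 CPM. Htr1b, a serotonin receptor, was higher by a log2 fold change of 2.37 ± 0.32. In lung, Htr1b was at 3.06 and 3.36 CPM in replicates 1 and 2 and at 0.905 and 1.28 CPM in replicates 3 and 4. Ltb4r1, a receptor for leukotriene B4, was at 183 ± 30.8 CPM in small intestine against 796 ± 48.8 in lung.

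Genes of cholesterol synthesis and of the interferon response were mostly higher in small intestine. All 16 genes of cholesterol synthesis were higher in small intestine (camera adjusted p = 8.04e-10, and adjusted p = 0.0681 with an estimated correlation). Among them, Cyp51 was at 347 ± 35.7 against 78.9 ± 9.68 CPM and Msmo1 at 134 ± 16.0 against 25.8 ± 6.29 CPM. Of 17 tested interferon response genes, 16 were higher in small intestine (camera adjusted p = 2.68e-09, and adjusted p = 0.072 with an estimated correlation). Oasl2 was at 23.3 ± 1.52 against 1.24 ± 0.546 CPM. Of 5 tested genes of the aryl hydrocarbon receptor pathway, 3 were higher (camera adjusted p = 0.000929, and adjusted p = 0.127 with an estimated correlation). Ahrr, the repressor of the receptor, was at 36.7 ± 11.1 against 0.124 ± 0.165 CPM and Nqo1, a quinone reductase, at 6.73 ± 1.90 against 0.146 ± 0.173 CPM. The counts of these 3 lists were the same adjusted over the list alone. Of 18 genes of ILC2 identity, 4 were higher and 8 lower in small intestine, also adjusted over the list alone (camera adjusted p = 0.141, and 0.027 within replicates 1 and 2). Gata3, the master regulator of type 2 lymphocytes, was higher by a log2 fold change of 0.59 ± 0.12 and Tcf7, a transcription factor of early innate lymphoid cells, by 1.76 ± 0.17, while the log2 fold change of Thy1 was -2.61 ± 0.41. Within replicates 1 and 2 the adjusted p of Gata3 was 0.0739. Arg1, which encodes arginase, was at 471 ± 27.1 against 966 ± 97.5 CPM. Rora was at 766 ± 102 against 767 ± 92.5 CPM (adjusted p = 0.994). The integrin genes Itgb7 and Itga4, whose products form the gut-homing receptor, did not pass the test, with log2 fold changes of -0.17 ± 0.10 and 0.44 ± 0.21 (adjusted p = 0.237 and 0.117). The adjusted p of Itga4 was 0.0274 without small intestine replicate 2 and 0.0368 within replicates 3 and 4.

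Gzma, Nkg7 and Cd160, genes known from cytotoxic lymphocytes, were higher in small intestine. Gzma, which encodes granzyme A (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981, minus strand), was at 397 ± 98.8 CPM in small intestine and 0.274 ± 0.378 in lung. Nkg7 was at 688 ± 189 against 14.7 ± 3.25 CPM and Cd160 at 240 ± 11.1 against 1.58 ± 0.938 CPM. Markers of other cells moved with this comparison. Of 10 tested NK cell and ILC1 markers, 7 were higher in small intestine and 1, Ccl5, was lower (7 and 2 adjusted over the list alone). In the test of the list, the camera adjusted p was 0.00339, with an adjusted p = 0.259 with an estimated correlation. Of 10 tested T cell markers, 7 were lower in small intestine and 2 were higher, also adjusted over the list alone (camera adjusted p = 0.0652, and 0.0389 without small intestine replicate 2). Trac was among the lower ones at 0.839 ± 0.526 against 4.90 ± 0.795 CPM. The higher ones were Cd6, at 65.9 ± 4.82 against 7.49 ± 1.02 CPM, and Trbc1, at 323 ± 25.4 against 174 ± 31.3 CPM. Of 8 tested B and plasma cell markers, 4 were higher in small intestine (5 adjusted over the list alone). Camera gave an adjusted p of 0.00633, with an adjusted p = 0.279 with an estimated correlation and 0.0891 within replicates 3 and 4. Igha, the constant region of immunoglobulin A, was at 472 ± 291 CPM in small intestine and 50.2 ± 99.3 in lung. Its adjusted p was 0.0735 in the main fit, and became 0.000884 with the replicate number as a block and 2e-06 without lung replicate 4. Of 12 tested macrophage, monocyte and dendritic cell markers, 3 were higher in small intestine, also adjusted over the list alone, and H2-Ab1 was among them at 45.2 ± 8.29 against 7.41 ± 4.57 CPM. Camera gave this list an adjusted p of 0.062, which was 0.0244, 0.042 and 0.0389 without kidney replicate 1, lung replicate 3 and small intestine replicate 2 and 0.0389 with a prior count of 0.5. Its 17 genes summed to 210 to 313 CPM in small intestine and 41.1 to 72.0 CPM in lung. Of 10 tested genes of stroma and endothelium, 8 were higher in small intestine (9 adjusted over the list alone). The camera adjusted p was 0.00462, with an adjusted p = 0.43 with an estimated correlation. Pdgfrb, a receptor of pericytes and fibroblasts, was at 98.5 ± 20.1 against 0.427 ± 0.473 CPM. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads may be split by the counting, were at 98.8 ± 64.2 and 250 ± 169 CPM in small intestine against 1.5 ± 1.16 and 9.52 ± 6.20 in lung. Of the 27 tested genes of their list, immediate early and heat shock genes, 9 were higher and 7 lower in small intestine, also adjusted over the list alone (camera adjusted p = 0.324).

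Lung and small intestine libraries fell into replicates 1 and 2 and replicates 3 and 4, a division that no label explains and that was examined after seeing the data. Within replicates 1 and 2 the counts were 1537 higher in small intestine and 1537 higher in lung, and within replicates 3 and 4 they were 1638 and 1769, each with 4 libraries in place of 8. With a term for this division the counts were 2869 and 2811.

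**Figure D2:**
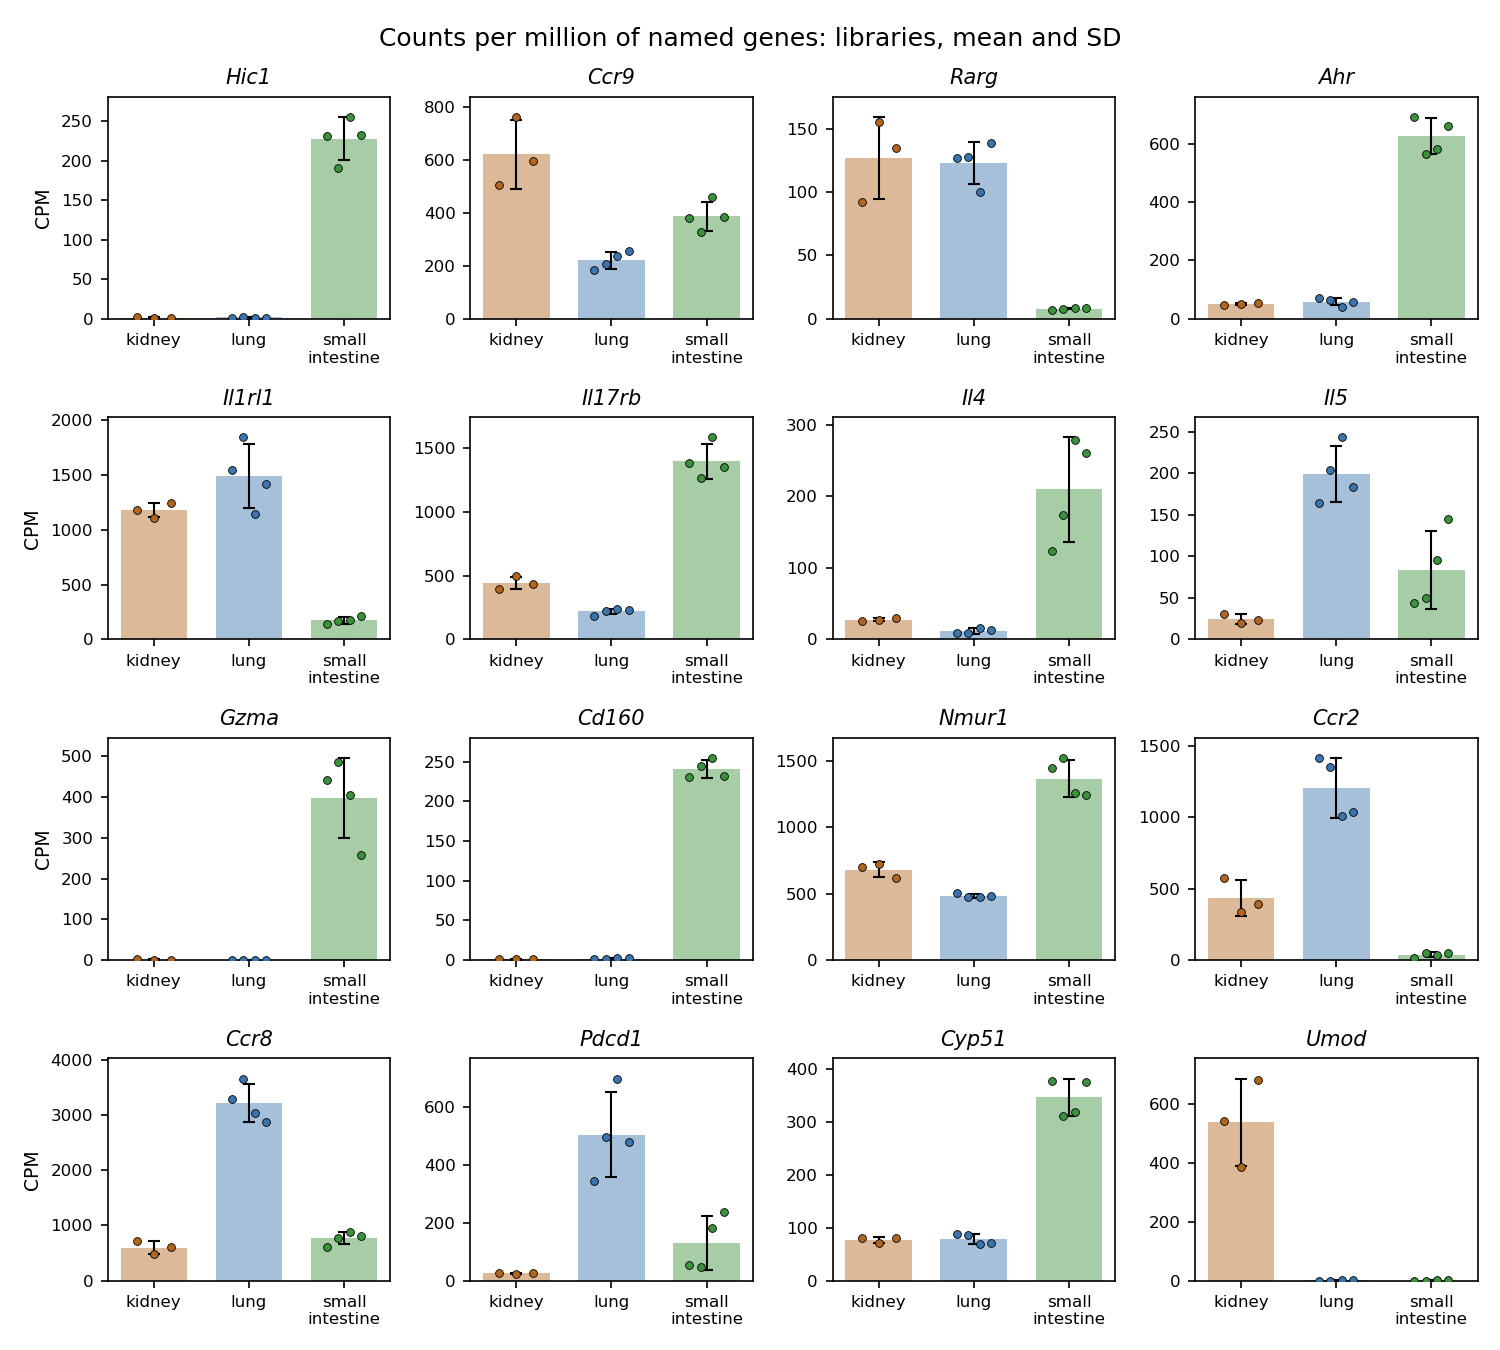
Each panel shows 1 named gene as TMM-scaled CPM (linear axis from 0) in kidney (3 libraries), lung (4) and small intestine (4). Points are libraries, bars are means and whiskers are the SD. Hic1 has a mean of 228 CPM in small intestine and means under 2 CPM in the other organs. Il1rl1 and Il17rb run in opposite directions between small intestine and the other organs, and Umod, a kidney tubule gene, has a mean of 538 CPM in kidney.

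Small-intestinal ILC2s differed from kidney ILC2s in 3689 genes, with 1591 higher in small intestine (715 of them at least 2-fold) and 2098 higher in kidney (1278 at least 2-fold). Dtx1, a Notch-induced ubiquitin ligase, was at 539 ± 101 CPM in small intestine and 1.04 ± 0.564 in kidney, and Nsg2 at 98.4 ± 8.43 against 0.266 ± 0.289 CPM. Atp8a2 was at 418 ± 38.4 against 1.85 ± 0.504 CPM and Cd160 at 240 ± 11.1 against 1.04 ± 0.556 CPM. The largest changes on the kidney side were in genes of the kidney tubule. Umod, which encodes uromodulin of the loop of Henle (ENSMUSG00000030963, chromosome 7, 119462711 to 119479282, minus strand), was at 538 ± 149 CPM in kidney and had 2 counts in all small intestine libraries together. The ratio was 9848 with a 95% counting interval of 3103 to 92560. Egf was at 326 ± 114 against 0.902 ± 0.356 CPM. Kap was at least 951-fold higher and Kcnj1, a renal potassium channel, at least 435-fold higher, since neither had a count in small intestine (floor of 3 counts over the group). All 13 tested genes of the kidney epithelium list were higher in kidney than in small intestine (camera adjusted p = 1.53e-19, and adjusted p = 0.012 with an estimated correlation). The counts were the same adjusted over the list alone. The sum of the 15 genes of the list was 1332 to 1495 CPM in the kidney libraries and 2.82 to 5.99 CPM in those of small intestine.

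Genes of the retinoic acid response, the aryl hydrocarbon receptor pathway and cholesterol synthesis were mostly higher in small intestine than in kidney. Hic1 was at 228 ± 27.2 against 1.36 ± 0.875 CPM (log2 fold change 7.36 ± 0.36, adjusted p = 6.89e-09). Tgm2 was at 217 ± 47.1 against 8.69 ± 7.42 CPM (log2 fold change 4.63, and 5.62 without kidney replicate 1), while Rarg was lower by a log2 fold change of -4.03 ± 0.18. Ccr9 was higher in kidney than in small intestine, at 622 ± 131 against 388 ± 54.7 CPM (log2 fold change -0.68 ± 0.17, adjusted p = 0.00684). This call was lost without kidney replicate 2 (adjusted p = 0.0538). Of the 7 tested response genes, 5 were higher and 2 lower in small intestine, with the same counts adjusted over the list alone. The list passed the test (camera adjusted p = 0.0375), with an adjusted p = 0.209 with an estimated correlation. The adjusted p was 0.0684, 0.0722 and 0.0655 without kidney replicate 2, lung replicate 4 and small intestine replicate 3, 0.253 and 0.0694 within replicates 1 and 2 and replicates 3 and 4 of small intestine and lung, 0.0582 with the replicate block and 0.0506 with a prior count of 0.5. Rxrg was higher in small intestine than in kidney, at 264 ± 51.3 against 44.2 ± 4.79 CPM. Ahr, the aryl hydrocarbon receptor, was at 626 ± 61.8 CPM in small intestine, 58.5 ± 13.3 in lung and 50.2 ± 4.07 in kidney. Of 5 tested genes of its pathway, 4 were higher in small intestine than in kidney, also adjusted over the list alone (camera adjusted p = 0.000298, and adjusted p = 0.0922 with an estimated correlation). Of 16 genes of cholesterol synthesis, 13 were higher (14 adjusted over the list alone). In the test of the list, the camera adjusted p was 1.57e-08, with an adjusted p = 0.072 with an estimated correlation. Cyp51 was at 347 ± 35.7 against 77.5 ± 5.71 CPM and Idi1 at 40.8 ± 6.96 against 14 ± 2.13 CPM.

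Il17rb and Il1rl1 differed from kidney in the same directions as from lung, with log2 fold changes of 1.66 ± 0.14 and -2.77 ± 0.17 (adjusted p = 7.39e-07 and 6.01e-08). Of 19 tested alarmin and cytokine receptors, 4 were higher and 6 lower in small intestine than in kidney (4 and 7 adjusted over the list alone; camera adjusted p = 0.528), and of 12 tested chemokine receptors, 1 was higher and 4 were lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.287). Il2rb, a receptor subunit for interleukin-2 and interleukin-15, was at 291 ± 32.3 CPM in small intestine and 50.8 ± 10.3 in kidney. Nmur1 was higher in small intestine by a log2 fold change of 1.01 ± 0.12, Gata3 by 0.58 ± 0.14 and Rora by 0.91 ± 0.14. Il5 was at 83.4 ± 47.2 against 24.4 ± 5.72 CPM (log2 fold change 1.77 ± 0.36, adjusted p = 0.002; 0.93 with replicates 1 and 2 and 2.31 with replicates 3 and 4 of small intestine and lung) and Il6 at 39.7 ± 21.8 against 2.84 ± 1.27 CPM. Areg was at 214 ± 181 against 186 ± 41.8 CPM (adjusted p = 0.83). Within replicates 1 and 2 of small intestine and lung it was lower in small intestine, by a log2 fold change of -1.61 (adjusted p = 0.00256), and within replicates 3 and 4 it was higher, by 0.99 (adjusted p = 0.00733). Among checkpoint and costimulatory receptors, 7 of 14 tested were higher and 3 lower (8 and 3 adjusted over the list alone). Camera gave an adjusted p of 0.00771, with an adjusted p = 0.43 with an estimated correlation. Pdcd1, which encodes PD-1, was at 129 ± 94.5 against 24.4 ± 1.07 CPM (log2 fold change 2.40, and 1.03 and 3.10 with replicates 1 and 2 or 3 and 4 of small intestine and lung) and Cd28 at 3.41 ± 1.63 against 0.451 ± 0.326 CPM. Of 27 tested cell cycle genes, 6 were higher, also adjusted over the list alone, and Tyms was among them at 26.2 ± 3.76 against 8.44 ± 2.08 CPM (camera adjusted p = 0.000566, and adjusted p = 0.279 with an estimated correlation). On the kidney side were the transporters of glucose, Slc2a3, at 322 ± 23.9 against 118 ± 3 CPM, and of lactate, Slc16a3, at 55.0 ± 8.68 against 14.2 ± 3.13 CPM. Itgae, the integrin that binds E-cadherin, was at 8.17 ± 2.39 in small intestine, 6.31 ± 1.03 in lung and 1.43 ± 0.423 CPM in kidney.

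Markers of macrophages, monocytes and dendritic cells also moved with this comparison. Of 12 tested, 11 were higher in kidney than in small intestine (12 adjusted over the list alone). The camera adjusted p was 0.000793, with an adjusted p = 0.43 with an estimated correlation. The sum of the 17 genes of the list was 1250 CPM in kidney replicate 1 and 332 and 317 in replicates 2 and 3, against 210 to 313 CPM in small intestine. C1qb, a complement gene of macrophages, was at 12.4 ± 14.6 against 0.523 ± 0.540 CPM, and its log2 fold change of -4.61 was -2.96 without kidney replicate 1. Of 10 tested T cell markers, 4 were higher and 2 lower in small intestine than in kidney (5 and 3 adjusted over the list alone; camera adjusted p = 0.1005, and 0.0356 without kidney replicate 1). Trbc1 was at 323 ± 25.4 against 14.5 ± 0.456 CPM and Cd6 at 65.9 ± 4.82 against 0.975 ± 0.490 CPM. Of 10 tested NK cell and ILC1 markers, 8 were higher in small intestine than in kidney and 1 was lower (9 and 1 adjusted over the list alone; camera adjusted p = 2.62e-06, and adjusted p = 0.0725 with an estimated correlation). Gzma was at 397 ± 98.8 against 0.474 ± 0.645 CPM and Nkg7 at 688 ± 189 against 10.7 ± 1.13 CPM. Of 8 tested B and plasma cell markers, 3 were higher in small intestine (4 adjusted over the list alone), among them Igha at 472 ± 291 against 0.436 ± 0.435 CPM. Their camera adjusted p was 0.0098, with an adjusted p = 0.32 with an estimated correlation and 0.0877 within replicates 3 and 4. Of 27 tested immediate early and heat shock genes, which can respond to the handling of cells, 9 were higher and 3 lower in small intestine than in kidney (10 and 4 adjusted over the list alone). This list had a camera adjusted p of 0.0397, with an adjusted p = 0.528 with an estimated correlation. The adjusted p was 0.0758, 0.0832 and 0.0778 without kidney replicate 2, small intestine replicate 3 and small intestine replicate 4, 0.394 within replicates 1 and 2 and 0.0564 with the replicate block. Within replicates 1 and 2 of small intestine and lung, the counts of the comparison with kidney were 1307 higher in small intestine and 1887 higher in kidney, and within replicates 3 and 4 they were 1605 and 2078.

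Lung ILC2s differed from kidney ILC2s in 2659 genes, with 1069 higher in lung (465 at least 2-fold) and 1590 higher in kidney (968 at least 2-fold). Effector genes were mostly on the lung side. Of 17 tested effector genes, 10 were higher in lung and 1 lower (11 and 1 adjusted over the list alone). In the test of the list, the camera adjusted p was 0.000153, with an adjusted p = 0.429 with an estimated correlation. Il5 was at 199 ± 33.8 CPM in lung and 24.4 ± 5.72 in kidney (log2 fold change 3.03 ± 0.38, adjusted p = 7.68e-05), and Ccl1 at 545 ± 204 against 28.1 ± 11.5 CPM. The lower one was Il4, at 11.5 ± 3.92 against 27.3 ± 1.90 CPM. Of 19 tested alarmin and cytokine receptors, 8 were higher in lung and 1 lower (10 and 1 adjusted over the list alone). Camera gave an adjusted p of 6.52e-05, with an adjusted p = 0.0277 with an estimated correlation. Il2rb was at 320 ± 36.4 against 50.8 ± 10.3 CPM and Ifngr1, a receptor subunit for interferon gamma, at 678 ± 46.8 against 198 ± 26.3 CPM. Il17rb was higher in kidney (log2 fold change -1.02 ± 0.13). Il1rl1 was at 1488 ± 292 against 1178 ± 65.6 CPM and did not pass the test (adjusted p = 0.195), but did within replicates 1 and 2 of lung and small intestine (adjusted p = 0.0257). Ccr8 was at 3219 ± 346 against 596 ± 119 CPM and Ccr4 at 45.9 ± 5.27 against 14.6 ± 3.73 CPM.

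Other genes higher in lung were Pdcd1, at 504 ± 145 against 24.4 ± 1.07 CPM, and Lrrn2, at 33.9 ± 3.77 against 0.357 ± 0.186 CPM. Bace2, an aspartyl protease, was at 62.7 ± 4.5 against 3.28 ± 0.287 CPM. Tubb6 was at 127 ± 21.2 against 6.72 ± 0.836 CPM and Mettl24 at 30.9 ± 4.62 against 1.04 ± 0.546 CPM. Of 18 genes of ILC2 identity, 8 were higher in lung, and adjusted over the list alone 8 were higher and 1 lower. The camera adjusted p was 0.00894, with an adjusted p = 0.279 with an estimated correlation. Kit was at 865 ± 252 against 207 ± 16.2 CPM, and Rora and Arg1 were higher by log2 fold changes of 0.91 ± 0.14 and 0.93 ± 0.14. Gata3 did not differ beyond the spread (adjusted p = 0.964). Of 14 tested checkpoint and costimulatory receptors, 9 were higher in lung and 2 lower, also adjusted over the list alone (camera adjusted p = 0.000793, and adjusted p = 0.35 with an estimated correlation). Of 10 tested genes of the transforming growth factor beta response, 4 were higher and 1 lower (7 and 1 adjusted over the list alone). In the test of the list, the camera adjusted p was 0.00426, with an adjusted p = 0.279 with an estimated correlation. Pmepa1, an inhibitor of that pathway, was at 35.6 ± 11.2 against 6.03 ± 1.93 CPM. The immediate early gene Egr3 was at 16.7 ± 4.55 against 0.788 ± 0.294 CPM and the transcription factor Bach2 at 37.5 ± 3.12 against 8.90 ± 2.43 CPM. T cell markers moved with this comparison, and 7 of 10 tested were higher in lung, also adjusted over the list alone (camera adjusted p = 8.1e-07, and adjusted p = 0.0149 with an estimated correlation). Among them, Trbc1 was at 174 ± 31.3 against 14.5 ± 0.456 CPM and Cd6 at 7.49 ± 1.02 against 0.975 ± 0.490 CPM.

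On the kidney side, Ccr9 was at 622 ± 131 against 220 ± 32.1 CPM (log2 fold change -1.50 ± 0.17, adjusted p = 3.32e-05), and Nmur1 was at 679 ± 56.0 against 484 ± 15.7 CPM. Tgm2 was also higher in kidney (log2 fold change -2.08, adjusted p = 0.00688). The call was lost within replicates 3 and 4 of lung and small intestine (log2 fold change -1.60, adjusted p = 0.098), and the log2 fold change was -1.09 without kidney replicate 1 (adjusted p = 0.0368). Of 7 tested retinoic acid response genes, 4 were higher in kidney, also adjusted over the list alone. The list passed the test (camera adjusted p = 0.0291), with an adjusted p = 0.198 with an estimated correlation. The call was lost without kidney replicate 1, 2 or 3 (adjusted p = 0.156, 0.0615 and 0.0796), without lung replicate 4 (0.0746) and without small intestine replicate 3 or 4 (0.0595 and 0.0797), as well as within replicates 1 and 2 and within replicates 3 and 4 of lung and small intestine (0.0811 and 0.0714). Of 17 tested interferon response genes, 13 were higher in kidney (15 adjusted over the list alone). Camera gave an adjusted p of 4.41e-09, with an adjusted p = 0.072 with an estimated correlation. Oasl2 was at 8.89 ± 3.11 against 1.24 ± 0.546 CPM and Ifi44 at 5.29 ± 2.20 against 0.161 ± 0.0829 CPM. Hspa1a and Hspa1b were at 118 ± 73.5 and 308 ± 187 CPM in kidney, while 7 of the 27 tested genes of their list were higher in lung and 5 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.336). Cpa3, a mast cell protease, was at 134 ± 16.9 CPM in kidney, 51.1 ± 10.4 in lung and 1.02 ± 0.563 in small intestine. Of the markers of other cells, all 13 tested kidney epithelium genes were higher in kidney than in lung (camera adjusted p = 2.2e-24, and adjusted p = 0.0108 with an estimated correlation). So were all 12 tested macrophage, monocyte and dendritic cell genes (camera adjusted p = 1.29e-07, and adjusted p = 0.277 with an estimated correlation). The counts of both lists were the same adjusted over the list alone. Of 10 tested genes of stroma and endothelium, 5 were higher in kidney (8 adjusted over the list alone). The camera adjusted p was 0.00232, with an adjusted p = 0.43 with an estimated correlation. H2-Ab1, a class II gene of antigen-presenting cells, was at 131 ± 111 against 7.41 ± 4.57 CPM. Its kidney mean rests on replicate 1, with 259 CPM against 72.8 and 61.6 in replicates 2 and 3, and its log2 fold change of -4.15 was -3.19 without that library. Without kidney replicate 2, the genes higher in lung numbered 674 in place of 1069. Within replicates 1 and 2 of lung and small intestine the counts were 977 higher in lung and 1477 higher in kidney, and within replicates 3 and 4 they were 1318 and 1587.

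**Figure D3:**
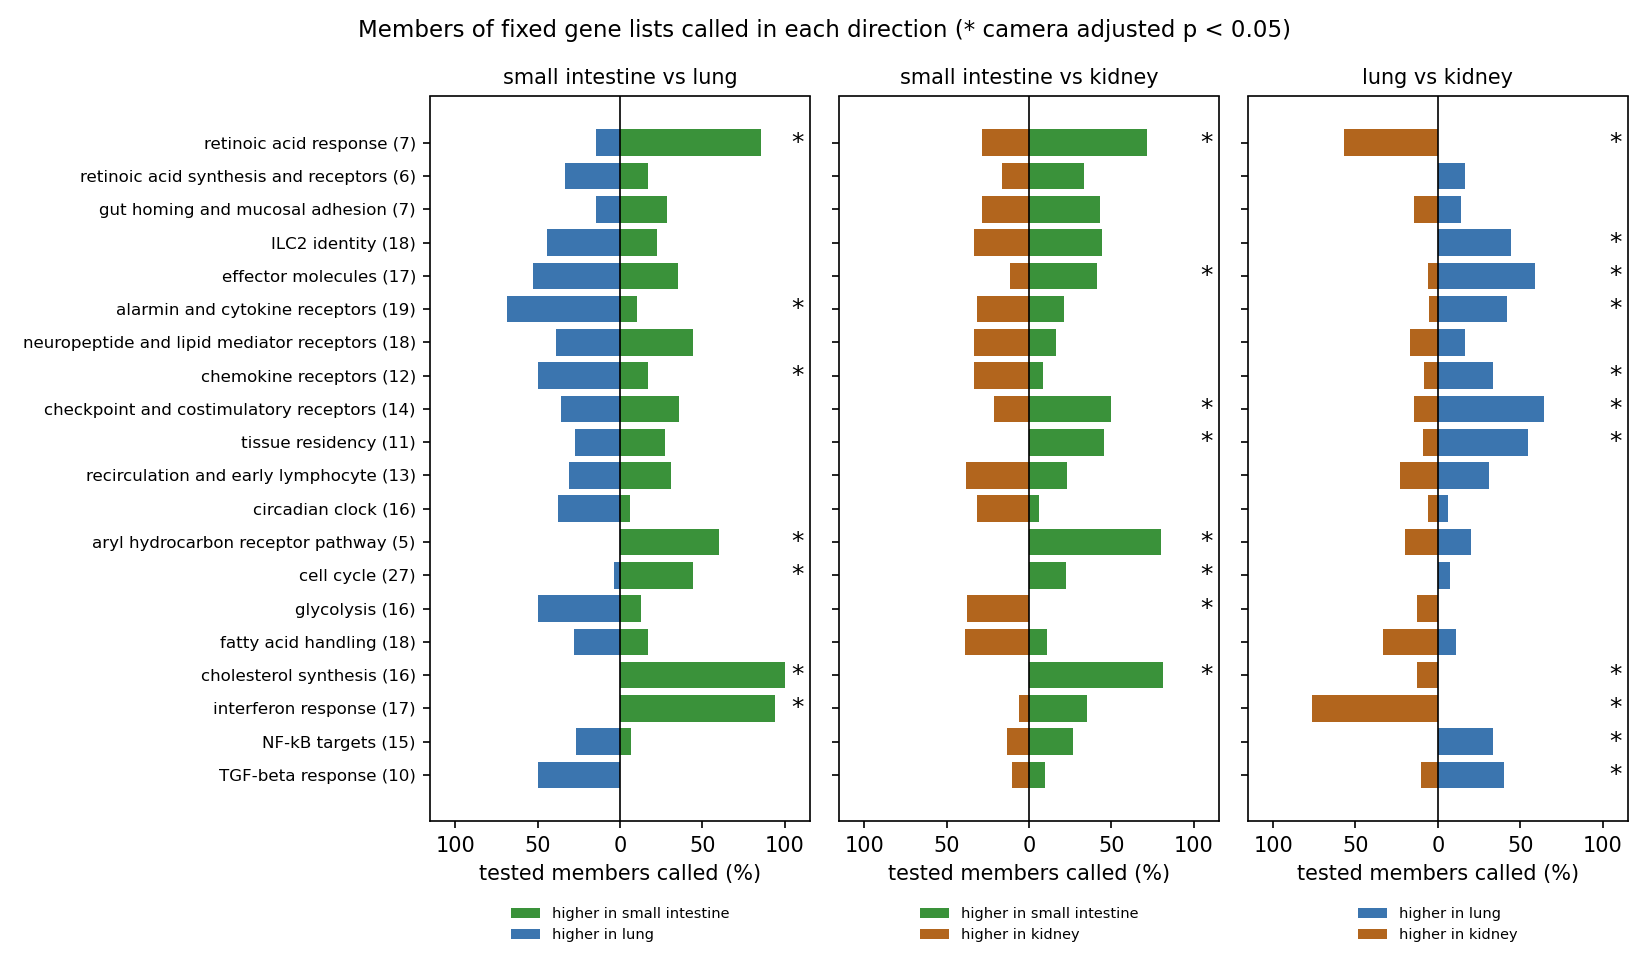
Bars give the percentage of tested members of each gene list, fixed before the data were examined, that were called higher in the first organ (to the right) or in the second organ (to the left), 1 panel per comparison, with the number of tested members after each name. A star marks a camera adjusted p under 0.05 with the preset correlation. All 16 genes of cholesterol synthesis and 16 of 17 interferon response genes are higher in small intestine than in lung.

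Genes were called particular to an organ when they differed in the same direction from both others. Small intestine had the most, with 1052 higher and 1230 lower than in both lung and kidney, among them Hic1, Ahr, Gzma, Nkg7, Il4, Il17rb and Gata3 on the higher side and Il1rl1, Rarg, Sema4a, Ccr2 and Ramp1 on the lower side. Lung had 618 higher, with Ccr8, Ccl1, Il5, Arg1 and Pdcd1 among them, and 774 lower. Kidney had 721 higher, with Umod, Ccr9, Slc2a3 and Cpa3 among them, and 341 lower, with Il2rb and Ccr4 among them. The latter count was 193 without kidney replicate 2 and 520 with limma-voom. Since the 2 comparisons of an organ share its libraries, simulated unchanged groups were counted the same way and gave at most 1 gene. Almost no gene is called in unchanged groups, so this cannot show how far shared libraries raise the overlap among genes that differ. Without regard to the shared libraries and the shared organ, independent lists of the same lengths would share 291 and 378 genes for small intestine. For lung these numbers were 193 and 290.5, and for kidney 251 and 128. Within replicates 1 and 2 of lung and small intestine the counts were 740 and 883 for small intestine, 496 and 575 for lung and 665 and 262 for kidney, and within replicates 3 and 4 they were 831 and 931, 565 and 565, and 756 and 482.

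Across the 13291 tested genes, the log2 fold changes of small intestine over lung and over kidney correlated with r = 0.466 and a covariance of 0.849. Genes are not independent replicates, and the shared small intestine libraries alone gave r = 0.461 ± 0.016 and a covariance of 0.048 ± 0.002 (SD of 20 simulations of unchanged groups), so that the covariance exceeded the simulated one by 0.802. With the small intestine libraries divided between the comparisons, r was 0.304 to 0.529 and the covariance 0.647 to 0.969 over the 6 divisions. In these divisions, where the 2 comparisons shared no library, 676 to 794 genes were higher in both and 722 to 864 lower. Independent lists of the same lengths would share 129.7 to 249.3 and 167.7 to 295.8 genes. Small intestine still stood on the same side of both comparisons. Any real difference of its profile therefore raises r, the covariance and the overlap, even if lung and kidney are unrelated. These values thus cannot show that lung and kidney are alike.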

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

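No test in this part was chosen after its result was seen, but some of the genes it covers were. In each group of 4 libraries, the highest or lowest value was set against the others for the genes named in the text, the library totals and the share of ribosomal protein genes. Of 202 groups of values, 10 had a value far from the other 3, and chance alone sets about 1 group in 20 apart. Kidney, with 3 libraries, was not tested.

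In small intestine, Ly6a was at 525 CPM in replicate 4 and at 668 to 687 CPM in the others. Ccr4 was at 366 CPM in small intestine replicate 4 and at 239 to 257 CPM in the others. Itgb7 was at 1527 CPM in small intestine replicate 4 against 1896 to 1971 CPM. Kit was at 282 CPM in small intestine replicate 3 against 422 to 441 CPM. In lung, Il7r was at 703 CPM in replicate 2 against 627 to 636 CPM. Cd28 was at 3.85 CPM in lung replicate 2 against 5.24 to 5.43 CPM. Jchain, which encodes the joining chain of immunoglobulins, was at 38.2 CPM in lung replicate 4 and at 0.259 to 0.296 CPM in the other lung libraries. Igha was at 199 CPM in the same lung library and at 0.437 to 0.647 CPM in the others. Egf was at 1.42 CPM in lung replicate 3 against 0.0728 to 0.296 CPM. C1qb was at 0.291 CPM in lung replicate 1 and had no count in the other lung libraries.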

How the results depend on the processing

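The tests within replicates 1 and 2 or 3 and 4 and the term for this division were chosen after their need was seen in the data; the other alternatives were set before the data were examined. A result was counted as kept when it stayed on its side of the threshold. It also had to keep its direction if either fit called it, while a change of direction without a call was not counted. Of 303 results of named genes, 303 were kept with size factors in the manner of DESeq2, 303 with a filter of 10 counts in 3 libraries, 302 with no filter, 296 with DESeq2, 293 with limma-voom and 296 with the replicate block. Fits of 2 organs alone kept 286 of 290 and the term kept 92 of 94. The subsets kept 284 (replicates 1 and 2) and 282 (replicates 3 and 4) of 303. With 1 library left out, 3264 of 3333 were kept, 36 lost and 33 gained the call, and no called result turned. Of 90 pairs of list and comparison, 90 were kept with the other size factors, 88 with a prior count of 0.5, 85 with the block, 57 with an estimated correlation, 66 with fry and 78 and 84 in the subsets. The other size factors moved the median log2 fold change by 0.0019, -0.0069 and -0.0088 in the 3 comparisons, and 4798 of the 4823 genes called between small intestine and lung were called with them in the same direction. Most simulated 1.5-fold changes were missed, but far fewer genes were changed there than were called here. How many small changes were missed in these data is not known.

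Genes lower in kidney than in both other organs numbered 520 with limma-voom and 193 (without kidney replicate 2) to 337 with 1 library left out. Genes higher in lung than in kidney numbered 674 (without kidney replicate 2) to 1062. The fit without kidney replicate 2 held only 2 kidney libraries, but so did those without kidney replicate 1 or 3. Between lung and kidney, 1977 genes were called without kidney replicate 2, against 2253 and 2167 without kidney replicates 1 and 3. The cause was not tested, nor was that of the count with limma-voom. Between small intestine and lung, replicates 1 and 2 alone gave 1537 and 1537, with 4 libraries in place of 8. At an adjusted p under 0.01, a stricter threshold by construction, 1561 genes were higher in small intestine and 1583 in lung, 930 in small intestine and 1384 in kidney, and 569 in lung and 1002 in kidney. An estimated correlation called 5 pairs of list and comparison and fry 60, where the first asks the same question with another correlation between genes and fry asks another question. With the small intestine libraries divided, the correlation between its 2 comparisons was 0.304, 0.354 and 0.317 in the divisions that set replicate 1 and another against lung; the cause was not tested. The first 2 components held 77% of the variance over all tested genes, a wider set than the 500 most variable. Areg turned to -1.61 between small intestine and kidney within replicates 1 and 2 (adjusted p = 0.00256, and 0.00256 to 0.983 over its 20 alternatives). It was 0.99 within replicates 3 and 4 (adjusted p = 0.00733), and the cause was not tested. Camera did not call the list of retinoic acid synthesis and receptors between small intestine and lung (adjusted p = 0.931, mean log2 fold change 0.158). Fry, which asks another question, called it upward (adjusted p = 0.0307, and 0.0307 to 0.993 over the list's 18 alternatives).

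With the replicate block the counts were 2580 and 2548 for small intestine against lung, 1574 and 2101 for small intestine against kidney and 1067 and 1559 for lung against kidney. Between small intestine and lung, the block added calls of Ptprc, Igha and C1qa (adjusted p = 0.044, 0.000884 and 0.027, with ranges over the alternatives of 0.00981 to 0.66, 2e-06 to 0.304 and 0.00936 to 0.267). In the comparisons with kidney, same-numbered libraries did not all correlate positively. There the block ended the calls of Ptprc and Ifi44 against small intestine (adjusted p = 0.0813 and 0.0567) and added Il13 (0.0422), and Isg15 against lung (0.00666). Among lists it ended those of retinoic acid response, glycolysis and immediate early and heat shock genes between small intestine and kidney (0.0582, 0.0711 and 0.0564) and of chemokine receptors between lung and kidney (0.0505), and added interferon response between small intestine and kidney (0.0434). The calls of glycolysis (0.0472) and of these chemokine receptors (0.0259) were also lost with an estimated correlation (0.209 and 0.43), and that of glycolysis without any 1 of 7 libraries (kidney 1 to 3, lung 1 and 4, small intestine 1 and 2; 0.0512 to 0.0684). The block changed no other call of a named gene or list.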

Other observations

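The tests of explanations for the kidney genes, the division of the libraries and the cytotoxic genes were chosen only after those patterns were seen, and the counts over other splits of the libraries were set before. Klf2, a transcription factor of lymphocyte recirculation, was at 380.5 ± 160.5 CPM in small intestine, 27.8 ± 5.22 in lung and 91.1 ± 5.39 in kidney, a log2 fold change of 3.78 ± 0.29 against lung. Of 13 tested genes of recirculation and early lymphocytes, 4 were higher and 4 lower in small intestine than in lung (4 and 7 adjusted over the list alone; camera adjusted p = 0.601). Isg15 was at 70.2 ± 29.4, 8.48 ± 4.37 and 15.7 ± 0.208 CPM in small intestine, lung and kidney. It belongs to the interferon response list, of which 6 of 17 tested genes were higher and 1 lower in small intestine than in kidney (7 and 2 adjusted over the list alone). The camera adjusted p of this list was 0.0821. It was 0.0227 and 0.0453 without kidney replicate 1 and without small intestine replicate 4, 0.0232 within replicates 1 and 2 and 0.0434 with the replicate block. Dbp, an output gene of the circadian clock, was at 28.3 ± 2.23, 56.3 ± 7.94 and 61 ± 7.16 CPM. Of 16 tested clock genes, 1 was higher and 6 were lower in small intestine than in lung, also adjusted over the list alone (camera adjusted p = 0.0936, and 0.042 and 0.0232 without lung replicate 3 and within replicates 1 and 2). Of 11 tested tissue residency genes, 5 were higher in small intestine than in kidney (5 higher and 1 lower adjusted over the list alone), and 6 were higher and 1 lower in lung than in kidney. The camera adjusted p of 0.0138 and 0.00524 became an adjusted p = 0.43 and 0.365 with an estimated correlation, and the first was 0.0994 within replicates 1 and 2. Of 15 tested targets of NF-kB, 5 were higher in lung than in kidney (7 adjusted over the list alone; camera adjusted p = 0.00866, and adjusted p = 0.488 with an estimated correlation).

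The genes of this paragraph were chosen after their values were seen and are given in the order small intestine, lung and kidney. The integrin subunit Itgb2 was at 114 ± 31.6, 527 ± 6.93 and 342 ± 10.8 CPM (log2 fold change of small intestine over lung -2.21 ± 0.17), and the subunit Itgb3 at 373 ± 76.7, 178 ± 60.4 and 171 ± 53.6 CPM. Batf, a transcription factor of activated lymphocytes, was at 179 ± 34.2, 65.6 ± 10.1 and 64.9 ± 0.266 CPM. Slc7a8, an amino acid transporter, was at 514 ± 52.1, 1458 ± 139 and 1739 ± 281 CPM. P2rx7, a receptor for extracellular ATP, was at 77.1 ± 11.2, 24.8 ± 6.45 and 55.2 ± 12.8 CPM, higher in small intestine than in lung by a log2 fold change of 1.64 ± 0.19, with an adjusted p of 0.0911 against kidney that was 0.0381 without kidney replicate 2 (0.0381 to 0.261 over the alternatives). Klrb1b, a lectin-like receptor, was at 139 ± 53.6, 10.2 ± 2.64 and 28.4 ± 3.55 CPM, and Cst7, which encodes cystatin F, at 102 ± 22.4, 22.4 ± 4.22 and 9.52 ± 2.6 CPM.

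In each comparison, 1 of 35 splits of the libraries called as many genes as the real one, the real split itself. The other splits mix libraries of different organs, which widens the spread, so that few genes are called. The splits therefore cannot exclude chance differences between the mice or preparations behind each organ. The real and highest other counts were 4823 and 106 for small intestine against lung, 3689 and 718 for small intestine against kidney and 2659 and 215 for lung against kidney. The split with 106 genes set replicates 1 and 2 of lung and small intestine against the rest, which points to a structure of the samples. It parted none of the 4 pairs of same-numbered libraries; of the 8 splits that part all 4, the 7 others called 0 genes. The same limit holds for genes particular to an organ. Among 100 splits of the 11 libraries, 1 gave as many genes particular to kidney (1062, highest other 1) and 1 as many particular to small intestine (2282, highest other 0). For genes particular to lung, 2 splits gave as many (1392), the real one included. The other of these 2, with 1787 genes, held the 4 small intestine libraries together as a group.

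Of 721 genes higher in kidney than in both other organs, 400 were under 1 CPM elsewhere, among them 12 of the kidney epithelium list and 6 of the macrophage, monocyte and dendritic cell list. All 13 tested genes of the kidney epithelium list were higher than in both others, with Umod at 538 CPM, so that RNA of tubule cells may account for part of the 400, although the CD45 beads and the gate would remove such cells; of the 15 genes of the list, 15 were at 1 CPM or more in kidney and 1 in each other organ, and none is in another list. Macrophage RNA cannot be told apart for these 400 genes or for the other 321, at 1 CPM or more elsewhere, since the test rests on kidney replicate 1 alone: there the macrophage list was at 3.85 times its mean in replicates 2 and 3, the 400 genes at a median of 1.22 times (quartiles 0.869 and 2.23) and the 321 at 1.04 times (quartiles 0.871 and 1.40). For the 321, RNA of tubule cells cannot be told apart either, since the kidney epithelium list varied by only 1.12 times between kidney libraries. A difference of kidney ILC2s themselves was not tested and stays open for both sets.

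Between replicates 1 and 2 and replicates 3 and 4 of lung and small intestine, 1676 of 12271 tested genes differed, 980 higher and 696 lower in the latter, and of 109 ribosomal protein genes 83 were higher and 1 was lower. GC content and gene length as the whole cause are argued against, since 2427 genes were called after a correction that moved log2 fold changes by a median of 0.0347, with 1554 of the 1676 among them. Library size as the whole cause is argued against by 1554 genes called after thinning to the smallest total. A shared preparation batch cannot be told apart, since no label gives a day or batch; the share of counts on ribosomal protein genes was separated by 0.68 percentage points. No biological explanation was tested.

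The cytotoxic genes Gzma, Nkg7 and Cd160 could come from other lymphocytes in the small intestine sort. T cells cannot be told apart, since their markers did not move together. Cd3d, Cd3e, Cd3g and Trac were all lower in small intestine than in lung (median log2 fold change -2.1, from -2.51 to -1.61). Cd6 and Trbc1 were higher in small intestine than in lung. Against kidney, Cd3g was higher (log2 fold change 1.06 ± 0.17). Trac was lower than in kidney, a call lost without kidney replicate 1, kidney replicate 2 or small intestine replicate 1. In small intestine, Cd3d was at 0.219 to 1.66 CPM and Trac at 0.109 to 1.32 CPM. Cd3e and Cd3g, chosen after their values were seen, were at 6.59 ± 1.54 and 63.7 ± 14.2 CPM there. The lineage gate would remove T cells. Of the 14 genes of their list, 9, 10 and 8 were at 1 CPM or more in kidney, lung and small intestine. NK cells or ILC1s in the sort cannot be told apart either, since 7 of the 10 tested genes of their list were higher in small intestine, 5 of them besides Gzma and Nkg7, its most abundant genes at 397 ± 98.8 and 688 ± 189 CPM, and Ccl5 was lower at 5.06 ± 2.07 against 19.9 ± 9.99 CPM; the lineage gate would remove NK cells, 3, 8 and 10 of the 12 genes of the list were at 1 CPM or more in kidney, lung and small intestine, and 2 are in another list. The KLRG1 gate of the small intestine sort also cannot be told apart, with a log2 fold change of Klrg1 of 0.63, since no organ was sorted with both gates. A difference of small-intestinal ILC2s themselves was not tested and stays open.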
